A study of Mus musculus with 2 samples.

How the data were processed

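ATAC-seq was done on liver tissue of mice at postnatal day 0 in 2 biological replicates, each a pool of animals, with Nextera tagmentation and a fragment size range of 200 to 750 bp, per the labels. The labels number the replicates as biological replicates with separate sample records but 1 shared donor label, so shared animals or litters cannot be excluded. Peaks are on mm10, per the labels. The aligner, the peak caller, their versions, any shift of read ends to the transposase cut and any filter on reads are not given in the sources used here.

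The authors deposited 3 peak lists per replicate and 6 for the series. The IDR-thresholded lists and the conservative set are in narrowPeak format with 10 columns, and each line is 1 summit, so that a peak interval with several summits takes several lines. The authors' score column in these lists holds a scaled irreproducible discovery rate (IDR): it was at least 540, which stands for a global IDR of 0.05, and at most 1000, and it matched the global IDR in the ranked lists to within 1. In the pseudoreplicated and replicated lists the score is instead a scaled −log10 p. The authors' signal value is a measure of peak strength whose normalization is not given in the sources used here, and the deposited −log10 p is the caller's p-value for the peak. Both were used only to rank, filter or describe peaks within a list, except for the rank correlation between replicates. Per the README files, the thresholded lists were derived from the alignments and 1 further input file whose content is not stated. The conservative set holds peaks of 1 of the 2 ranked lists of the series that have a score of at least 540. In the ranked lists of the series 16 columns hold per-sample values that no label maps to a replicate, and these were not used. No read counts were given, so depth is unknown and cannot be compared between the replicates.

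Overlapping peaks were merged into regions, each with the summit of its strongest peak. The main set for genes, classes and motifs was the series' conservative set. Regions of the replicates were compared by an overlap of at least 1 bp between their IDR-thresholded lists, against 100 circular shifts of the other replicate's regions within each chromosome. Gene positions came from the GENCODE vM21 basic annotation, with 53365 TSSs of 32093 protein-coding and long noncoding genes, and sequences from the GRCm38.p6 assembly, the same build as mm10, whose chromosome ends no peak exceeded. A promoter region overlapped the 1000 bp on either side of a TSS, and a distal region overlapped no such window. A gene's territory was its body plus 50000 bp on either side.

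The comparisons, the 26 gene lists, the 21 motif consensus sequences and the alternatives were set before the data were examined. The lists cover hepatocyte functions, fetal and adult liver genes, blood lineages, other liver cell types, housekeeping genes and other organs, and 447 list genes were matched to the annotation. The symbols G6pc1, Hbb-b1, Ahsp and Loricrin were not matched, and Tf was matched to Trf, already in its list. Promoter shares were compared with all other protein-coding genes by Fisher's exact test. Mean numbers of distal regions were compared with 100000 random lists of the same size drawn from protein-coding genes of the same decile of territory length, a permutation test. Motif shares in 200 bp windows at distal summits were compared by Fisher's exact test with windows 1000 bp downstream that lay outside every deposited peak. The share of replicate 1 regions without overlap in replicate 2 was compared between each list's territories and other regions by Fisher's exact test. Tests were two-sided, with Benjamini-Hochberg adjustment over lists or motifs and a threshold of 0.05. Genes, regions and windows are not replicates and neighbouring regions are not independent, so the p-values describe these libraries only. With 1 group there was no comparison between groups, no pairing and no regrouping of samples.

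Named genes were, for each list, the 3 members with the most distal regions (ties in alphabetical order) and up to 2 members without a promoter region in alphabetical order, the 10 protein-coding genes with the most distal regions per 100 kb of territory, and the nearest gene of the 10 peaks with the highest signal value outside the mitochondrial chromosome. Not all of them are printed. Alternatives were other peak sets, a stricter IDR of at most 0.01 (a score of at least 830, 32286 regions), each replicate's own peaks, other promoter windows and territories, 1 member per gene cluster, other motif windows and backgrounds, other definitions of overlap, and equal numbers of peaks. Chosen after seeing the data were matching on gene density, on promoter CpG content (observed over expected CpG within 500 bp of the TSS) and on signal value, and equal numbers of regions. Matches of peak sequences to the mitochondrial genome (blastn) and to other chromosomal sites (megablast) needed 90% identity over at least 50% and 80% of the interval. Equal numbers of regions was added because equal numbers of the strongest peaks removed mostly secondary summits and left 35769 of the 36781 replicate 1 regions.

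The code was tested on simulated data. In simulated regions over 21940 genes, 2 of 2 planted promoter lists and 1 of 1 planted distal list were recovered, with 0 of the other lists called. In simulated sequences 3 of 3 planted motifs were recovered, with 0 unrelated motifs called. The simulated second replicate was a random subset of the first one's regions, so correct code had to return the share kept. The overlap found was 70.1% where 70.1% had been kept. The 1 list given more missing regions was recovered with 0 others called. Background distal positions were uniform, sequences were random with equal bases, and missing regions did not depend on signal value. The simulations thus check the code and not the effect of clustering, GC content or signal value. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1, BLAST 2.17.0+ and matplotlib 3.10.9.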

Results

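Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in the liver of newborn mice at postnatal day 0. The series held 1 group of 2 biological replicates and no control or contrasting group. Replicate 1 came from the livers of 15 mice and replicate 2 from pooled livers whose number of mice the labels do not give. Both carry the same donor label, and whether the pools share animals or litters is not given, so the spread between them may be partly technical. Both pools mixed male and female animals, and the labels give the strain as B6NTac;B6NCrl/Lap. The deposited files list peaks and hold no read counts, so the read depth of each library is unknown and no interval that needs it is given. The design implies 3 questions: how far the replicates' accessible regions coincide, which genes and cell types those regions surround, and which transcription factor motifs lie under them. All coordinates are on mm10 and counted from 1.

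Replicate 1 held 36781 accessible regions covering 26.2 Mb and replicate 2 held 28039 regions covering 19.9 Mb, a mean of 32410 ± 6182 (SD, n = 2). The conservative set of the series, which requires reproducibility between the replicates, held 40259 regions covering 29.1 Mb, with a median length of 679 bp. In this set 61.6% of the regions carried several summits. Of the replicate 2 regions, 94.4% overlapped a replicate 1 region, and 71.3% of the replicate 1 regions overlapped a replicate 2 region. Circular shifts of the other replicate's regions along each chromosome gave mean overlaps of 2.04% and 1.57%, and no shift of the 100 exceeded 2.33% and 1.81%. With equal numbers of the strongest regions in each replicate, a setting chosen after seeing the data, the shares were 82.2% and 81.0%. For ranks, the peaks of both replicates were joined into common regions, a unit unlike those of the shares above. Across the 25998 common regions with a peak from each replicate, the authors' signal values ranked alike. Spearman's rho was 0.93 across regions, which are not independent replicates.

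Accessible regions were concentrated at promoters. Summits within 1 kb of an annotated transcription start site (TSS) made up 33.3% of the conservative set, against 2.64% of genome bases, a 12.6-fold excess. Introns held 38.1% of summits, intergenic sequence 25.2% and exons 3.32%. Intergenic summits were 0.455 times as frequent as the intergenic share of the genome. Promoter regions also had the higher signal value given by the authors, with a median of 14.3 against 8.72 in introns and 9.17 in intergenic sequence. The promoter share was 35.4% in replicate 1 and 42.3% in replicate 2, a mean of 38.8% ± 4.87 (SD, n = 2). Chromosome X had 4.79 regions per Mb, below the autosomes, which ranged from 11.6 to 23.5 regions per Mb with chromosome 11 the densest. In the wider replicated peak list the promoter share was 22.2%.

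**Figure D1:**
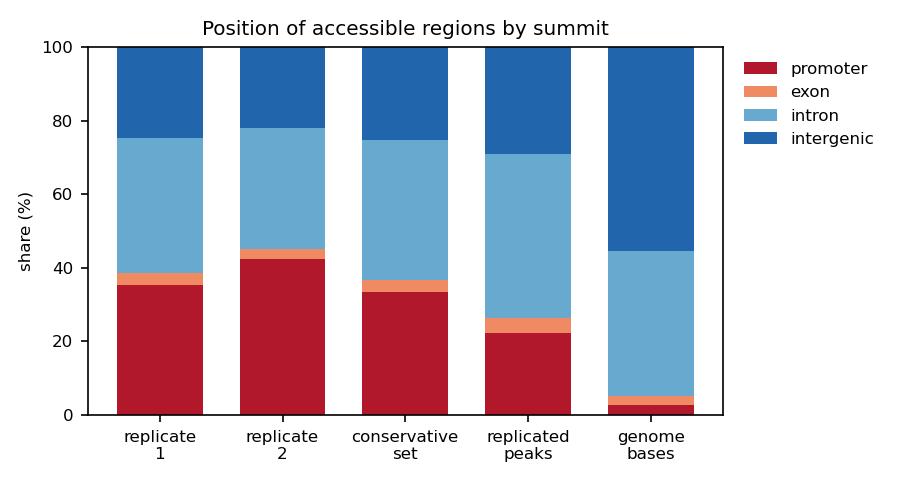
Share (%) of accessible regions whose summit lies in a promoter (within 1 kb of a TSS), exon, intron or intergenic sequence, for each replicate, the conservative set and the replicated peaks, beside the share of genome bases. Promoters took 35.4% of the replicate 1 and 42.3% of the replicate 2 regions but 2.64% of the genome.

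Genes of hepatocyte function carried promoter regions more often than other genes. A region of the conservative set lay within 1 kb of a TSS for 12406 of the 21938 protein-coding genes (56.6%). For secreted plasma proteins the count was 22 of 23 genes, for liver transcription factors 18 of 20, for gluconeogenesis and glycogen 14 of 16, for the urea cycle and amino acid catabolism 14 of 16, and for fatty acid oxidation and ketogenesis 16 of 16. Each of these shares was higher by Fisher's exact test, two-sided and adjusted by Benjamini-Hochberg over the 26 lists, with adjusted p = 0.000376, 0.00478, 0.0187, 0.0187 and 0.000624. The urea cycle list missed the threshold in the series' less strict set (exact test, adjusted p = 0.0965). Members without a promoter region included Apoc3, an apolipoprotein gene, Hnf1b and Nr0b2 among the transcription factors, Gpd1 and Sds in gluconeogenesis, and Otc and Tdo2 in amino acid catabolism. All 7 had a promoter region in the replicated and the pooled pseudoreplicated peaks, and Apoc3, Gpd1 and Sds had one in replicate 1. Genes are not replicates, so these tests describe the 2 libraries.

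Distal regions, over 1 kb from any TSS, were also more numerous around these hepatocyte genes. Counted within the gene body plus 50 kb on either side, secreted protein genes had a mean of 5.43 distal regions against 2.28 ± 0.512 (SD over random lists) in random lists matched on territory length, a ratio of 2.38 (permutation test, two-sided, adjusted p = 0.00052, from an unadjusted 2e-05, the smallest that 100000 permutations can give). The ratio was 2.17 for liver transcription factors, 1.92 for fatty acid oxidation, 1.89 for gluconeogenesis and 1.84 for the urea cycle list (permutation tests, adjusted p = 0.0109, 0.0109, 0.0277 and 0.0208). Albumin (Alb; chromosome 5, 90460897 to 90476602) had 10 distal regions, and the fibrinogen chain genes Fga and Fgb had 9 each in overlapping territories. The strongest of the Alb regions lay at 90447343 to 90448215, upstream of the gene, with a signal value of 20.1. Among the transcription factors, Nr5a2 had 10 distal regions, 8 of them in its gene body, and Hnf4a and Rxra had 9 each. Pcx, which encodes pyruvate carboxylase of gluconeogenesis, had 10 distal regions and Aldob and Fbp1 had 8 each. Hpd of tyrosine catabolism had 9, and the urea cycle genes Asl and Cps1 had 8 each. Hadha and Hadhb, the adjacent genes of the mitochondrial trifunctional protein, had 10 each, and Hmgcs2, the ketogenic HMG-CoA synthase, had 9. With territories of 100 kb on either side, the gluconeogenesis and urea cycle lists missed the threshold (permutation test, adjusted p = 0.0627 and 0.0696), and gluconeogenesis did so with the replicated peaks (permutation test, adjusted p = 0.0736).

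Bile acid genes and genes that mature after birth had more distal regions than matched lists in the conservative set, without a promoter excess that passed there. The bile acid list had a distal ratio of 2.03 (permutation test, adjusted p = 0.0152), with 8 regions each at Akr1d1 and Cyp8b1 and 7 at Abcg8, while 11 of its 14 genes had a promoter region (Fisher's exact test, adjusted p = 0.145). The bile acid promoter share did pass in the series' less strict set (12 of 14), the replicated peaks (14 of 14) and replicate 1 alone (12 of 14), with adjusted p = 0.0467, 0.0068 and 0.0406 in Fisher's exact tests. Cyp7b1 had neither a promoter region nor a distal region, and Baat had 7 distal regions without one at its promoter, while both had a promoter region in the replicated and pooled pseudoreplicated peaks. For adult hepatocyte genes the distal ratio was 1.75 (permutation test, adjusted p = 0.0272), and 10 of 17 had a promoter region (Fisher's exact test, adjusted p = 1). Cyp1a2 and Rnase4 had 9 distal regions each and Cyp3a11 had 7, whereas Cyp1a2 and Cyp2b10 lacked a promoter region in the conservative set. Cyp2b10 had one in the replicated peaks and Cyp1a2 only in the pooled pseudoreplicated peaks. The adult list's distal call was lost with the peaks of either replicate alone (permutation test, adjusted p = 0.058 from replicate 2 and 0.115 from replicate 1), and also with the replicated peaks, a stricter IDR and both other territories (permutation tests, adjusted p = 0.11, 0.0681, 0.0605 and 0.0646). The bile acid call was lost with territories of 10 kb or 100 kb on either side (permutation test, adjusted p = 0.197 and 0.0627). Against random lists matched on promoter CpG content, chosen after seeing the data, both lists had more promoter regions (permutation test, adjusted p = 0.000347 and 0.000371).

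Erythroid genes stood beside the hepatocyte genes. Of the 36 erythroid genes matched, 35 had a promoter region (Fisher's exact test, adjusted p = 1.33e-06), and the distal ratio was 1.89 (permutation test, adjusted p = 0.0152). Zfpm1, which encodes the GATA cofactor FOG1 (chromosome 8, 122282141 to 122337251), had 13 distal regions, 8 of them in its gene body. Slc25a37, the mitochondrial iron importer mitoferrin, had 9, as did Gfi1b, which alone of the list lacked a promoter region in the conservative set and had one in the replicated peaks. Both calls held with each alternative peak set, window, territory and matching tried, including each replicate's own peaks.

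**Figure D2:**
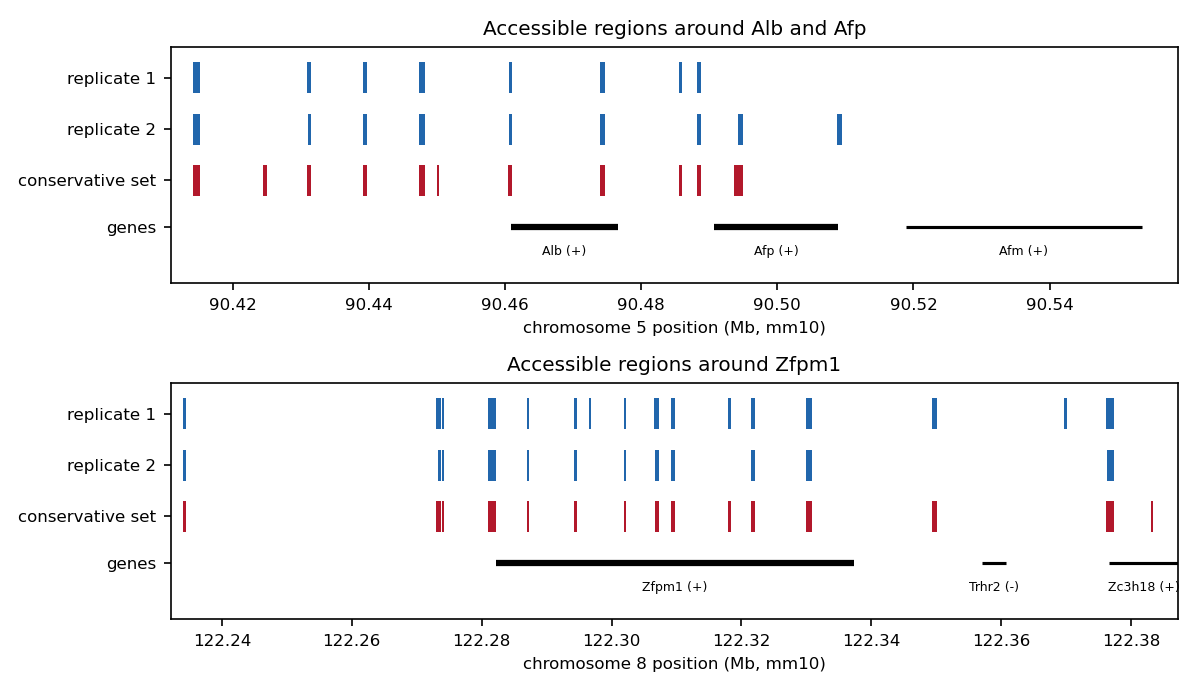
Position (Mb, mm10) of accessible regions in replicate 1, replicate 2 and the conservative set around Alb and Afp on chromosome 5 and Zfpm1 on chromosome 8, with protein-coding genes drawn as black bars and their strand in brackets. The conservative set held 11 regions in the Alb and Afp window and 15 in the Zfpm1 window, promoter regions included.

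Genes of other blood and liver cell types did not share this excess. Promoter regions were present for 4 of 20 neutrophil and monocyte genes, 5 of 18 Kupffer cell genes, 0 of 9 mast cell genes, 1 of 15 B lymphoid genes, 2 of 15 T and NK lymphoid genes and 4 of 21 endothelial genes, each a lower share than in other genes (Fisher's exact tests, adjusted p = 0.00271, 0.0241, 0.00201, 0.000394, 0.00268 and 0.00201). The stem and progenitor list (10 of 17), the megakaryocyte list (6 of 15), the stellate list (9 of 20) and the cholangiocyte list (7 of 16) did not pass the test (Fisher's exact tests, adjusted p = 1, 0.254, 0.416 and 0.382). None of these 10 lists passed the distal test (permutation tests, adjusted p from 0.147 to 1). With a promoter window of 2.5 kb the neutrophil and Kupffer promoter calls ended as well (Fisher's exact tests, adjusted p = 0.0595 and 0.0512). Single members had many distal regions: Eng, an endothelial coreceptor, had 11, the sinusoidal scavenger receptor gene Stab2 had 10, Lyl1 of the progenitor list had 10, Vwf and Gp9 of the megakaryocyte list had 9 each, and Spi1, which encodes the myeloid factor PU.1, had 8. Cd34, Cd19, Cpa3 and Col3a1 had neither kind of region in the conservative set, and of these Cd34 had a promoter region in the replicated and pooled pseudoreplicated peaks. With the wider replicated peaks, the neutrophil, Kupffer and B lymphoid promoter calls ended (Fisher's exact tests, adjusted p = 0.579, 0.678 and 0.159) and the endothelial promoter share turned to a log2 odds ratio of 1.18 (Fisher's exact test, adjusted p = 0.164). Matched on promoter CpG content, chosen after seeing the data, the endothelial list alone of these 6 passed (permutation test, adjusted p = 0.0302), and the neutrophil and Kupffer shares turned above their matched means, by log2 ratios of 0.31 and 0.20.

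Genes of other organs had few promoter regions, and housekeeping genes had them throughout. Housekeeping promoters were accessible for 24 of 24 genes (Fisher's exact test, adjusted p = 2.79e-05), a call that ended with matching on promoter CpG content (permutation test, adjusted p = 0.063). The count was 1 of 19 for heart and skeletal muscle, 3 of 18 for neuron, 3 of 15 for pancreas, 2 of 11 for lung epithelium and 1 of 11 for keratinocyte (Fisher's exact tests, adjusted p = 2.93e-05, 0.00271, 0.0128, 0.0202 and 0.00345), while the intestinal list at 3 of 11 did not pass (Fisher's exact test, adjusted p = 0.0917). Matched on CpG content, the muscle and neuron lists stayed lower (permutation tests, adjusted p = 0.0302 and 0.000173) and the other 3 did not pass. The lung call also ended with a promoter window of 2.5 kb (Fisher's exact test, adjusted p = 0.18). Distal regions of the lung epithelium list had a ratio of 1.66, which did not pass (permutation test, adjusted p = 0.147). Neuron genes had the only distal ratio below 1 that passed, 0.461 (permutation test, adjusted p = 0.0336), a call lost with the peaks of replicate 1 or replicate 2 alone (permutation test, adjusted p = 0.0548 and 0.0912), with territories of 10 kb or 100 kb (0.0772 and 0.0815) and with matching on gene density (0.107). Housekeeping genes had a distal ratio of 1.56 (permutation test, adjusted p = 0.0452), which turned below 1 with 10 kb territories (log2 ratio -0.22) and missed the threshold with replicate 2 alone, 100 kb territories or gene density matching (permutation tests, adjusted p = 0.0919, 0.0701 and 0.0816). Fetal and imprinted liver genes passed neither test, at 9 of 14 promoters (Fisher's exact test, adjusted p = 0.653) and a distal ratio of 1.45 (permutation test, adjusted p = 0.226). H19, Igf2bp3 and Meg3 had 8 distal regions each. Afp, which encodes the fetal serum protein alpha-fetoprotein, had 6 distal regions, all of them also within the territory of its neighbour Alb and counted there too. Dlk1 had 6, and neither Afp nor Dlk1 had a promoter region in the conservative set. Dlk1 had one in the replicated and pooled pseudoreplicated peaks and Afp in neither.

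**Figure D3:**
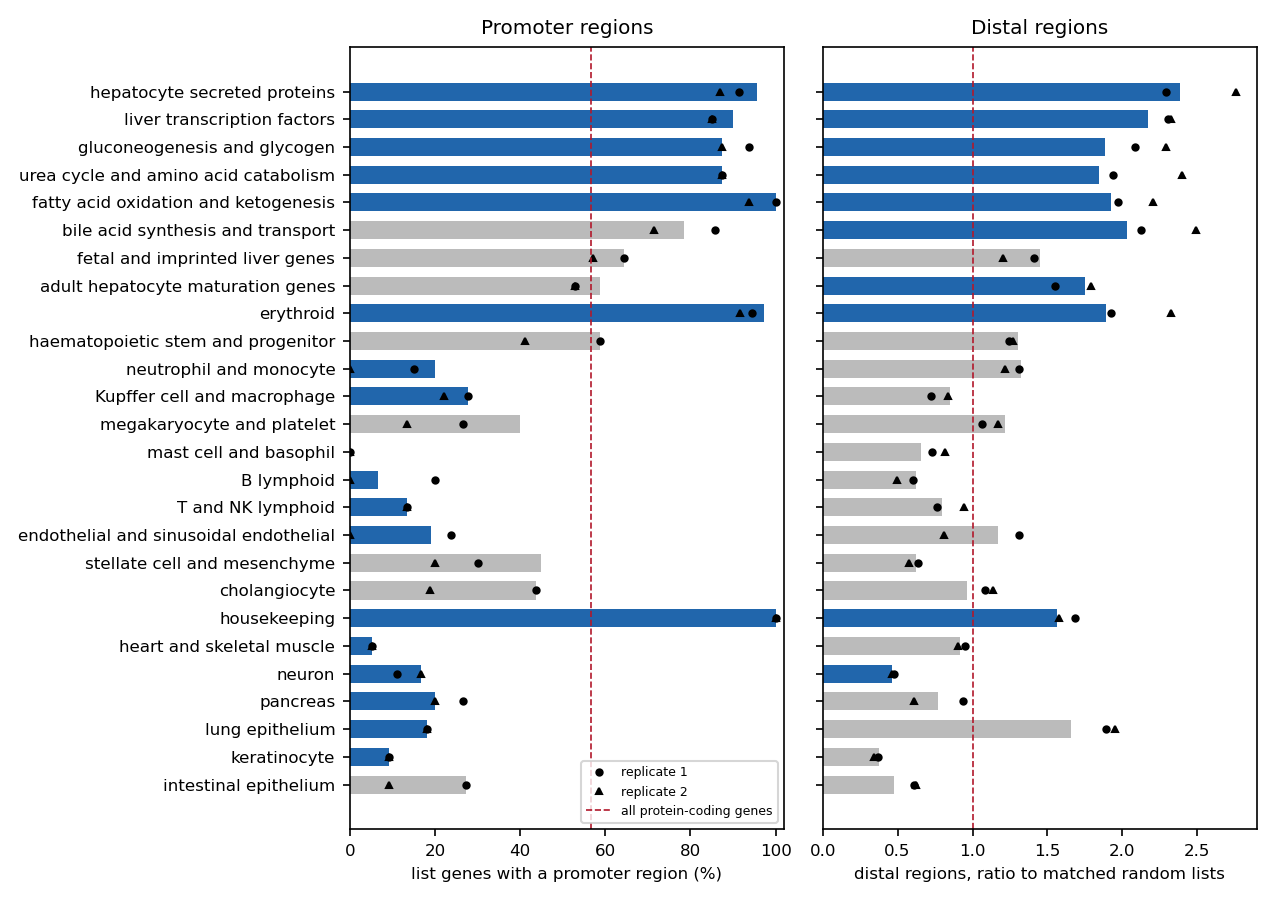
Left, share (%) of each list's genes with a region within 1 kb of a TSS, and right, mean number of distal regions as a ratio to random lists matched on territory length. Bars show the conservative set, blue where the adjusted p was under 0.05, with circles for replicate 1, triangles for replicate 2 and dashed lines at 56.6% and at a ratio of 1. Hepatocyte and erythroid lists lie to the right of both lines, as do the housekeeping, the fetal and imprinted, and the stem and progenitor lists.

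Nearly all motifs searched were more frequent at distal summits than beside them, those of hepatocyte and erythroid transcription factors among them. Among 26244 windows of 200 bp centred on distal summits, the HNF4A consensus CAAAGTCCA was found in 2.02%, against 0.227% of the 23780 windows 1 kb downstream (odds ratio 9.04, Fisher's exact test, adjusted p = 9.07e-90). The odds ratio was 5.85 for HNF1, 4.14 for CEBP, 2.65 for FOXA and 1.66 for ONECUT, the other hepatocyte factors searched. For GATA, present in 7.83% of windows against 2.53%, it was 3.27 (Fisher's exact test, adjusted p = 6.28e-162), for the GATA-TAL composite 5.43 and for NFE2 7.54. The excess was not specific to these lineages: the odds ratio was 4.47 for CTCF, the insulator protein, and 2.08 for the E-box of muscle and neural factors, found in 17.3% of windows against 9.15%. The odds ratio was 2.65 for AP-1 and 2.4 for KLF, which are not clear of the erythroid motifs. The NFE2 consensus contains the AP-1 consensus, so each NFE2 match is also an AP-1 match. KLF is set beside GATA for erythroid territories below. Of the 21 motifs, 20 were more frequent at summits and REST, found in 3 windows, did not pass (Fisher's exact test, adjusted p = 0.252). TEAD had the smallest excess, an odds ratio of 1.1 (Fisher's exact test, adjusted p = 0.0331), a call that also ended with replicate 2's peaks alone, 100 bp windows and windows 1 kb upstream (Fisher's exact tests, adjusted p = 0.66, 0.703 and 0.252). The RFX call ended with replicate 1's peaks alone (Fisher's exact test, adjusted p = 0.0725). Summit windows had a mean GC content of 50.9% against 45.1% in the background, and with GC-matched windows NFY and TEAD no longer passed (Fisher's exact tests, adjusted p = 0.43 and 0.0565), while the odds ratio was 10.6 for HNF4A, 25.8 for HNF1 (103 windows against 4), 6.32 for CEBP, 3.93 for GATA and 7.5 for CTCF. In that setting it fell to 1.58 for KLF, 5.43 for NFE2 and 2.34 for SP, which had 4.35 before matching.

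**Figure D4:**
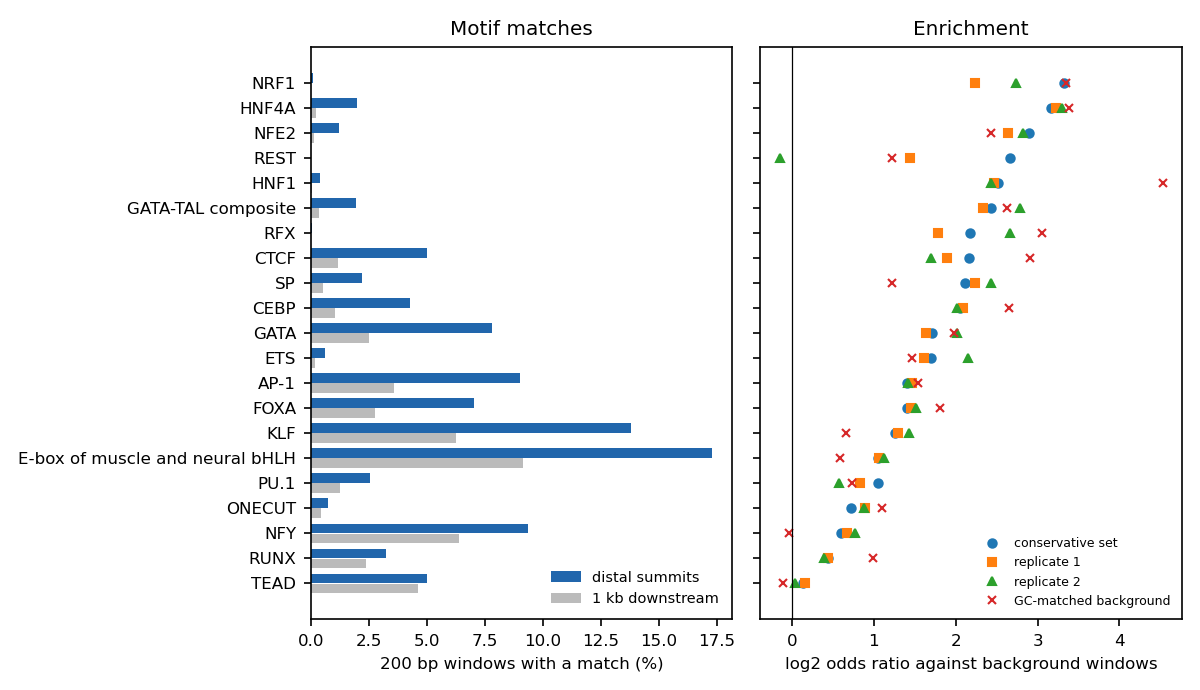
Left, share (%) of 200 bp windows with a motif match at distal summits and in windows 1 kb downstream, and right, log2 odds ratio for the conservative set, each replicate's own peaks and GC-matched background windows. HNF4A matches fell in 2.02% of summit windows against 0.227%, and GATA matches in 7.83% against 2.53%.

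In the IDR-thresholded lists, regions of endothelial territories were more often called in replicate 1 and missing from replicate 2 than other regions. Of 114 replicate 1 regions in endothelial territories, 55 were missing (48.2%), against 28.6% of the other regions (odds ratio 2.33, Fisher's exact test, adjusted p = 0.00026). Erythroid territories lost fewer, 49 of 276 regions (17.8%) against 28.7% (odds ratio 0.535, Fisher's exact test, adjusted p = 0.000411), and the other 24 lists did not pass. Shares in those lists ran from 18.5% (22 of 119, fatty acid oxidation) to 44.2% (19 of 43, pancreas). A share near the endothelial one thus also came from genes of another organ. Missing regions had a lower median signal value in replicate 1, 7.58 against 13.5 in shared regions, and 15.4% of them touched a promoter window against 45.5% of shared regions. With permutations matched on replicate 1 signal value, chosen after seeing the data, the erythroid call held (permutation test, adjusted p = 0.00026) and the endothelial call did not (permutation test, adjusted p = 0.123). Fewer missing regions were not specific to erythroid territories there, since the secreted protein, urea cycle, fatty acid oxidation and gluconeogenesis lists passed too (permutation tests, adjusted p = 0.000347, 0.00026, 0.00507 and 0.0263). With equal numbers of the strongest peaks both calls held (Fisher's exact tests, adjusted p = 0.000455 for endothelial and 4.76e-05 for erythroid), and fatty acid oxidation passed with fewer (adjusted exact p = 0.000855). With equal numbers of the strongest regions, also chosen after seeing the data, the endothelial call ended at 30.8% (Fisher's exact test, adjusted p = 0.119), below the stellate (36.8%) and keratinocyte (42.9%) shares, which did not pass either (adjusted exact p = 0.0715 and 0.131). The erythroid, secreted protein and fatty acid oxidation lists had fewer missing regions in that setting (Fisher's exact tests, adjusted p = 1.9e-07, 0.0204 and 0.0204). With pseudoreplicated peaks neither held (Fisher's exact tests, adjusted p = 0.101 for erythroid and 0.985 for endothelial). Replicate 2 regions missing from replicate 1 are another quantity, and a low endothelial share there would not contradict the main call. Of 60 such endothelial regions 1 was missing (1.67%) against 5.57% of the others, and of 236 erythroid regions 8 (3.39%) against 5.58%. Neither passed (Fisher's exact tests, adjusted p = 0.821 for both). Other lists were called with pseudoreplicated peaks: heart and skeletal muscle had more missing regions (37.2% against 26.1%), and the gluconeogenesis, bile acid, adult hepatocyte and housekeeping lists had fewer (Fisher's exact tests, adjusted p = 0.0354 for each). These tests compare 2 libraries and not conditions.

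The 10 strongest peaks lay away from promoters, but 56 of the 100 strongest intervals were distal, against 65.2% of all regions of the conservative set. Of the 10 peaks with the highest signal value in the conservative set, 8 were intergenic and 2 intronic, and both replicates called each of them. The first lay on chromosome X at 143482934 to 143483182, with a signal value of 60.1, 35531 bp from the nearest TSS of a protein-coding gene, that of Pak3. The second lay on chromosome 2 at 69355469 to 69355735, 12987 bp from the TSS of Abcb11, the bile salt export pump gene, with a signal value of 58.9. A peak on chromosome 6 at 49236380 to 49236685 lay 21566 bp from Igf2bp3, which encodes an RNA-binding protein of fetal tissue. The nearest genes of the others were Rtl10, Cdh20, G6pd2, Epm2a, Gm5426, Hic2 and Myl12b, with Cdh20 and G6pd2 2140260 and 1765835 bp away. The protein-coding genes with the most distal regions per 100 kb were, in that order, Tmem107 with 16 regions, Borcs6 with 14, Glrx5 with 15, Vamp2 with 14, Adrb2 and Arl4d with 13 each, Btn2a2 with 14, Mrto4 and Aurkb with 13 each, and Trim8 with 14. Tmem107, Borcs6, Vamp2 and Aurkb are neighbours on chromosome 11. Glrx5 encodes a mitochondrial protein of iron-sulfur cluster assembly.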

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

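The tests of gene density and of endothelial territories, and the count of strongest peaks without a mitochondrial match, were chosen only after the results they bear on were seen, and the test of CpG content was chosen after the promoter shares were seen but before its own result.

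Peaks appeared outside the lists used for the comparisons. In the ranked list of replicate 1, 179 peaks passed the authors' threshold of 540 but were left out of the thresholded list, 53 of them on sequences outside the assembled chromosomes. In replicate 2 there were 183 such peaks, 42 of them outside the assembled chromosomes. Among these peaks the one with the highest −log10 p lay in the same interval in both replicates, on chromosome 1 at 24611586 to 24616155, with −log10 p of 8486 and 7807. That interval's sequence matched the mitochondrial genome. It was the 1 interval with such a match among 52 left-out intervals on assembled chromosomes in replicate 1 and among 64 in replicate 2.

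The 10 strongest peaks lay away from promoters, a pattern limited to the top of the list, since 56 of the 100 strongest intervals were distal against 65.2% of all regions. For mitochondrial DNA reads placed at nuclear copies, 2 of these 10 peaks matched the mitochondrial genome at 90% identity over at least 50% of the interval. They were those nearest to G6pd2 and Gm5426, against 0 of 100 random distal peaks. The count of 2 lay between the bounds set beforehand for and against this cause, so that rule left it undecided. The other 8, the rest of the same count, had no match, which argues only against this as the cause at all 10. For those 2 peaks it remains a candidate explanation. For reads shared between near-identical copies, 1 of the 10, the peak nearest to G6pd2, had another copy on the assembled chromosomes. That share was 10% against 1% of the random peaks (Fisher's exact test, p = 0.174), so the rule set beforehand did not decide. The other strongest peaks had no such copy, which argues against these copies as the cause at all 10. For the G6pd2 peak they remain a candidate, and copies outside the assembled chromosomes were not searched. Shorter or less similar repeats fell below the identity and length set for a copy. The median repeat-masked share was 23.0% in the 10 strongest peaks, 9.36% in the random peaks and 8.80% in the 100 strongest intervals. Whether such repeats raised the signal was not tested. Among the 100 strongest intervals, 21 had another copy and 5 matched the mitochondrial genome, against 1 and 0 of the 100 random distal peaks. These differences were not tested, and only 56 of the 100 strongest intervals were distal. No biological explanation was tested.

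Erythroid and hepatocyte genes both carried more regions than other genes, and none of the erythroid list's genes is in another list. Gene density was argued against as the whole cause, because the erythroid distal ratio was 1.74 with random lists matched on territory length and gene density (permutation test, adjusted p = 0.0189), from 1.89 before. CpG-rich promoters were argued against too, since the median CpG ratio was 0.306 in the erythroid and 0.231 in the secreted protein list, against 0.793 in housekeeping genes. Both kept a higher promoter share when matched on CpG content (permutation test, adjusted p = 0.000173 for both). Matching lowered their expected shares to 45.1% and 20.6%, from 56.5% in other genes. It thus made the excess easier to reach and was no strict test. A candidate explanation is erythroid cells within the newborn liver: GATA matches were found in 16.6% of 169 distal summit windows in erythroid territories and in 4% of 100 in secreted protein territories (odds ratio 4.77, Fisher's exact test, p = 0.00162), but the GATA-TAL composite (4.14% against 3%) and KLF (20.7% against 13%) did not pass (exact p = 0.749 and 0.138). Against all other distal windows the erythroid GATA share had an odds ratio of 2.36 and missed the threshold (Fisher's exact test, adjusted p = 0.0765). That adjustment ran over 546 pairs of list and motif, while the exact p of 0.00162 is unadjusted, so these p-values cannot be set side by side. Megakaryocyte (15.9% of 44) and intestinal (21.4% of 14) territories had GATA shares close to or above the erythroid one. The motif thus does not name the cell, and no sorted sample was analysed here.

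Replicate 2 had fewer regions than replicate 1. Of the 10542 regions called in replicate 1 only, 90.3% overlapped a peak of replicate 2's full ranked list, against 2.47% after shifts. A lower depth of replicate 2 predicted this and remains a candidate. The full list also holds peaks below the threshold, so lower enrichment at equal depth, or fewer cells carrying a region, would look alike. The test cannot tell these apart. Another mix of cell types in replicate 2 stays open: the share of missing regions differed by -0.944 percentage points between the pooled hepatocyte and pooled blood lists (95% interval -5.31 to 3.42), which met the bound set beforehand against it. That bound was too narrow, since it left out the endothelial list, whose regions were missing in 48.2%, and pooled erythroid territories with other blood lineages. A smaller share of endothelial cells cannot be told apart from weaker peaks, as 48.2% against a signal-matched 39.2% gave an adjusted p of 0.123 in a permutation test.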

How the results depend on the processing

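Settings that matched on gene density, CpG content or signal value, and equal numbers of regions, were chosen after seeing the data. The cause of the changes below was not tested. The overlap of replicate 1 regions with replicate 2, and of replicate 2 with replicate 1, moved to 73.9% and 92.0% with pseudoreplicated peaks, 72.3% and 93.3% with equal numbers of peaks, and 81.0% and 82.2% with equal numbers of regions. Spearman's rho was 0.95 with −log10 p and 0.916 with pseudoreplicated peaks. The number of lists with a lower promoter share, 11, became 7 with the replicated peaks and 3 with CpG matching, and ranged from 13 to 15 without 1 replicate, while the number with a higher share stayed between 7 and 8 under all alternatives. The 9 lists with more distal regions became 4 with 100 kb territories and 7 to 8 without 1 replicate. The 1 list with fewer distal regions became 2 with replicated peaks and 0 with 10 kb territories, 100 kb territories, gene density matching or without either replicate. Promoter, exon, intron and intergenic shares were 22.2%, 4.07%, 44.6% and 29.1% with replicated peaks, and 35.4% to 42.3%, 2.86% to 3.25%, 32.9% to 36.7% and 21.9% to 24.6% without 1 replicate. At an IDR of at most 0.01 the promoter share was 38.3% and the intron share 35.1%. A promoter window of 2.5 kb gave 39.0% promoter, 2.75% exon and 34.6% intron, and one of 500 bp 3.75% exon. The 20 motifs more frequent at summits became 18 to 20. Lists with more regions missing from replicate 2, 1 at first, became 0 with equal numbers of regions or signal matching. In the opposite direction, replicate 2 regions missing from replicate 1, the number was 0 as well, though that is another quantity. Lists with fewer missing regions, also 1, became 4 with pseudoreplicated peaks, 2 with equal numbers of peaks, 3 with equal numbers of regions, 5 with signal matching and 0 in the opposite direction. Called lists and motifs kept their direction and side of the threshold in 127 combinations with a setting for promoters, 70 for distal regions, 154 for motifs and 4 for missing regions, and missed the threshold in 14, 19, 3 and 5. Directions turned for these results: with CpG matching the promoter share of the neutrophil list (log2 ratio 0.31) and the Kupffer cell list (0.20), with replicated peaks the endothelial promoter share (log2 odds ratio 1.18), with 10 kb territories the housekeeping distal ratio (log2 -0.22), with GC-matched windows NFY (log2 odds ratio -0.036) and TEAD (-0.11), and with 100 bp windows TEAD (-0.034). For replicate 2 regions missing from replicate 1 the endothelial log2 odds ratio was -1.23, which is no reversal of the call because another quantity was counted. No paired analysis was possible because the series has 1 group. Dinucleotide shuffles were not run. Unknown depth limits every statement that a region is missing.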

Other observations

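The searches of promoter summits and of each list's territories, and the comparisons of motifs other than GATA between erythroid and secreted protein territories, were chosen only after the distal result was seen.

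Motifs were also searched at promoter summits. In 200 bp windows at promoter summits the odds ratio against windows 1 kb downstream was 89.0 for NRF1, 35.9 for ETS, 23.5 for SP, 8.33 for KLF and 4.24 for NFY. The NRF1 value is imprecise, as it rests on 209 of 14014 summit windows against 2 of 11761 background windows. These 5 motifs passed at distal summits too, with odds ratios of 12.2, 3.28, 4.35, 2.4 and 1.52, although NFY turned to 0.975 there with GC-matched windows (Fisher's exact test, adjusted p = 0.43). The distal NRF1 value also rests on few matches, 27 at summits against 2 in the background. Promoter and distal summits were not tested against each other, and no GC-matched background was run for promoter windows. GATA (0.678), RUNX (0.498), TEAD (0.666) and FOXA (0.816) were less frequent than in those windows, FOXA by the smallest margin (Fisher's exact test, adjusted p = 0.014). HNF4A (1.48) and CEBP (1.21) did not pass (Fisher's exact tests, adjusted p = 0.0925 and 0.0986).

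Distal windows of erythroid territories had fewer CEBP matches than those of secreted protein territories, 1 of 169 against 6 of 100 (odds ratio 0.0933, Fisher's exact test, adjusted p = 0.0407), the opposite of GATA. HNF4A was found in 1 of 169 against 5 of 100 and did not pass (Fisher's exact test, adjusted p = 0.0653). With each list set against all other distal windows, 0 of 546 pairs of list and motif passed (Fisher's exact tests, smallest adjusted p = 0.0765), and 28 had an unadjusted p under 0.05. An unadjusted threshold of 0.05 can let about as many of 546 tests pass without any difference, so the 28 are not read as a result.

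Afp had no region within 1 kb of its TSS in the conservative set, in either replicate's own list, in the replicated peaks or in the pooled pseudoreplicated peaks. The nearest region of the conservative set lay 1986 bp from the TSS, on chromosome 5 at 90488241 to 90488751, with a signal value of 11.2. Apoc3 also lacked a promoter region in the conservative set but had one in replicate 1 and in the replicated peaks.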
